A study of Homo sapiens with 16 samples.

How the data were processed

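RNA-seq was measured in 4 libraries of HEK293T cells, MeRIP-seq in 4 pulldowns with 4 inputs, a CRISPR screen in 3 libraries and editing at knockout sites in 1 sample. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts 1.6.0, DESeq2, MACS2 and MAGeCK were used with the builds hg38 and GRCh38, without a role stated for each tool. Per the labels, RNA-seq started from 1.3 µg and MeRIP-seq from 4 µg of total RNA, and fragments of the MeRIP-seq samples were pooled after adapter ligation and before the immunoprecipitation. The authors deposited RNA-seq values as raw counts per gene. The MeRIP-seq lists deposited by the authors give for each peak a ratio, the fold over the caller's background, and p and q as -log10 p-values. In the screen tables the authors deposited a normalised signal per guide, which is the guide's count scaled by a factor per library, with log2 ratios per guide and gene and p-values with FDR per gene. The knockout table deposited by the authors gives the fraction of reads in each class of alteration, without read numbers.

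RNA-seq counts of 60683 genes were read, of which 60370 had a current symbol and the other 313 held 0.201% to 0.217% of the counts. Genes were filtered with filterByExpr (minimum count 10), normalised with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 fold changes of STM2457 over DMSO with SE, and levels are CPM, counts scaled by the normalised library total, with SD. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 for the 28 of 32 lists with at least 3 tested members, with Benjamini-Hochberg adjustment over those lists. The 32 lists held 768 genes and shared 6, namely ABCC2, ATF3, DDIT4, SESN2, SLC2A1 and SLC7A11. They were drawn from textbook knowledge and covered m6A, metabolism, growth, stress and markers of other cell types. Lists, the tests of the comparisons, groups, the rule for named genes and all alternatives except that on summits were fixed before the data were examined. RNA-seq names were the 10 largest rises and 10 largest losses among called protein-coding genes with a mean log2 CPM (counts per library total, scaled) of at least 2 whose libraries did not overlap between groups, the members of the lists of m6A genes, glycolysis and pentose phosphate pathway, and up to 4 members of each other list with the smallest p.

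Intervals with several summits were counted as 1. A DMSO region was an interval present in both DMSO lists with at least 1 bp overlap on the same strand, and it was kept with an overlap in both STM2457 lists, lost with none and partly kept otherwise. Genes were assigned by their span without regard to strand, which the annotation did not give, and regions in several coding spans were set aside. Genes were then classed by their regions and tested with camera as further sets, and linear models of the log2 change on class, span and expression were fitted with statsmodels 0.14.6. Place in the transcript and sequence motifs were not analysed here, since no genome sequence or exon annotation was at hand.

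Guide values were divided by the smallest step of each library to recover reads, where 1 read was 1.13 with DMSO and 0.900 with STM2457, and 100% and 99.9961% of the values were whole within a tolerance of 0.05 read. The recovered reads had a median of 144 and 180 per guide over 77441 guides. Counts of this kind would allow a count test, which was not run because each arm had 1 library. The gene value was the median over guides of the log2 ratio of the deposited values with a pseudocount of 1, and it matched the authors' guide ratios within 0.00013 except for 472 guides at 0 in DMSO. Gene list medians were placed among 10000 random lists matched on mean guide count in 20 bins. Screen names were the first 10 genes in each direction of the authors' deposited table and members of the lists, by the same rule. The table held 19112 gene names, against 18360 genes per the labels. The screen library of day 0 and the summary of read totals, whose library names match no label, were not analysed here. In the knockout data, 1 entry without a guide name was left out.

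The procedure was tested on simulated data. In 13614 simulated genes with 2 libraries against 2, edgeR recovered 41 of 67 genes set to 1.5-fold, 51 of 67 set to 2-fold and 64 of 66 set to 4-fold, and 9 of 171 calls (5.26%) were false. A set of 20 genes shifted by 1.3-fold was called, and 0 of 10 others were. The simulated genes were drawn independently, so this says nothing of lists whose genes vary together. In the data the estimated correlation was 0.37 for the m6A writers, 0.64 for ribosomal proteins and -0.0501 for p53 targets. In simulated gene values of the screen the shifted list was found, and 2 of 29 other lists fell outside the range of 95% of random lists. Overlap classes were recovered for 3000 of 3000 simulated regions and reads for 20000 of 20000 simulated guides. The simulated regions lay far apart and overlapped their partners by construction, so their recovery checks the code alone.

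Alternatives were DESeq2 1.42.0, limma-trend, DESeq2 size factors, no filter on low counts, a replicate block, each library or peak list left out, an added log2 limit of 1, an estimated correlation and fry for lists, a -log10 q of at least 10, a fold of at least 4, other overlap rules, guides of at least 50 counts, the mean over guides, a pseudocount of 10, rescaled totals and other FDR limits. Where 1 library was left, it was assumed to vary like the other arm. Intervals on shares are 95% exact binomial intervals and cover counting error only. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for the rest.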

Results

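Human HEK293T cells, an established line derived from embryonic kidney, were treated with STM2457 or with its solvent DMSO. STM2457 is a small-molecule inhibitor of METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into RNA. The series title names cell proliferation, glycolysis and the pentose phosphate pathway as its subject. RNA-seq was made from 2 biological replicates with DMSO and 2 with 5 µM STM2457, both for 72 h. These libraries held 5162922 and 4712207 counted reads with DMSO and 5564846 and 4430490 with STM2457. MeRIP-seq, the sequencing of RNA fragments pulled down by an antibody against m6A beside an input, was made from 2 replicates per group. Its dose, treatment time and read depth are not given in the sources used here. A pooled CRISPR knockout screen held 1 library per arm after 14 days in DMSO or STM2457, with 13691419 and 17152104 reads recovered from the guide table. Sequencing of edited sites from knockout cells was 1 sample with 24 named guides. Replicates are called biological in the labels, which do not say whether they came from separate cultures.

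RNA-seq asked which genes changed with METTL3 inhibition. The genes with the largest losses included receptors, a collagen and a mitochondrial enzyme. FLT1, a receptor for vascular endothelial growth factor, fell from 13.9 ± 1.36 to 1.34 ± 0.375 CPM (normalised read count, mean ± SD, n = 2 and 2), a log2 change of -3.38 ± 0.36 (SE). NRP1, a co-receptor of the same ligands, fell from 32.3 ± 6.14 to 6.61 ± 0.270, and COL14A1, a collagen, fell from 46.3 ± 3.76 to 9.50 ± 0.516. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 53.8 ± 1.55 to 11.9 ± 0.654, a log2 change of -2.18 ± 0.16. The largest gains included SPNS2, an exporter of sphingosine 1-phosphate, from 7.0 ± 0.467 to 42.4 ± 5.55 CPM, and FEM1A, a substrate receptor of an E3 ubiquitin ligase, from 13.3 ± 1.71 to 53 ± 11.4.

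Of 13924 genes tested with edgeR, 3493 changed at an adjusted p under 0.05, 1881 higher and 1612 lower with STM2457. The adjusted p was 7.9e-10 for SPNS2, 1.0e-08 for FEM1A, 4.3e-07 for FLT1, 1.1e-09 for COL14A1 and 5.4e-10 for PCK2. Among the 10 named genes with the largest rises were also DNAAF1, a factor for assembly of ciliary dynein, at a log2 change of 2.65 ± 0.45, the potassium channel gene KCNJ14 at 2.51 ± 0.34 and the zinc finger gene ZIK1 at 2.30 ± 0.38. HSD17B1, an estrogen-forming dehydrogenase, rose by 1.93 ± 0.36 and DHRS2 by 1.81 ± 0.33. IL3RA rose by 2.25 ± 0.46, ESAM by 1.82 ± 0.44 and SIRT4 by 1.78 ± 0.49. Among the 10 largest losses were also OSTN, a secreted peptide of muscle and bone, at -3.39 ± 0.51, MDGA1 at -2.45 ± 0.38, ALKAL1, a ligand of the kinase ALK, at -2.38 ± 0.46, and MYOM2, a sarcomere protein, at -2.30 ± 0.39. The transcription factor HAND1 fell by 2.26 ± 0.38 and TMEM255A by 2.17 ± 0.28. The call of IL3RA ended without STM2457 replicate 1, at a log2 change of 1.24 and an adjusted p of 0.206. That of ESAM ended without the same library, at 0.0539, and with DESeq2, at 0.0798, and that of SIRT4 ended without DMSO replicate 2, at a log2 change of 1.12 and an adjusted p of 0.110, without STM2457 replicate 2, at 0.0858, and with DESeq2, at 0.110. Without DMSO replicate 1 SIRT4 was at 3.25, and without STM2457 replicate 1 ALKAL1 was at -4.20. DESeq2 called 1288 genes, of which 1280 were among the 3493. Without DMSO replicate 2 the count was 2119, and 509 of the 3493 changed by a log2 value of at least 1.

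Of the 8 tested members of the writer complex, 7 rose (7 when adjusted over the list alone), with a median log2 change of 0.52. RBM15B, an RNA-binding adaptor of the complex, rose from 113 ± 0.496 to 217 ± 2.44 CPM, a log2 change of 0.94 ± 0.07. METTL14, the partner of METTL3, rose from 39.0 ± 2.29 to 70.4 ± 3.87, at 0.85 ± 0.12, and RBM15 rose by 0.73 ± 0.09. WTAP rose by 0.53 ± 0.08, CBLL1 by 0.52 ± 0.12, VIRMA by 0.50 ± 0.09 and ZC3H13 by 0.22 ± 0.07. METTL3 itself was at 110 ± 10.2 with DMSO and 110 ± 1.6 with STM2457. The list test (camera) gave an adjusted p of 1.4e-08, and adjusted p = 0.455 with an estimated correlation. The call of ZC3H13 ended without DMSO replicate 1 (adjusted p 0.284), without DMSO replicate 2 (0.0629) and with DESeq2 (0.133).

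Of the 12 readers and erasers of m6A, 6 rose and 1 fell, also when adjusted over the list alone. YTHDF2, a reader that recruits the deadenylation machinery, rose by 0.70 ± 0.07, and the demethylases ALKBH5 and FTO rose by 0.66 ± 0.08 and 0.45 ± 0.10. YTHDF1 rose by 0.47 ± 0.10, YTHDF3 by 0.40 ± 0.08 and YTHDC1 by 0.26, while the reader IGF2BP3 fell by 0.42. The list was called at an adjusted p of 0.0143, with adjusted p = 0.483 with an estimated correlation and 0.115 without STM2457 replicate 2. YTHDC1 lost its call with DESeq2 (0.0926) and without DMSO replicate 1 (0.0866) or 2 (0.107), and IGF2BP3 with DESeq2 (0.0713) and without DMSO replicate 2 (0.120).

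Of 24 glycolysis genes tested, 10 fell and 1 rose (the same numbers when adjusted over the list alone), with a median log2 change of -0.29. PFKL, the liver-type phosphofructokinase, fell from 234 ± 20.7 to 153 ± 15.1 CPM, at -0.62 ± 0.08. PGK1, the first ATP-forming enzyme of the pathway, fell by 0.50 ± 0.06, and GAPDH fell from 1512 ± 31.7 to 1105 ± 35.8, at -0.45 ± 0.07. LDHA, which turns pyruvate into lactate, fell by 0.42 ± 0.08 and PKM by 0.40 ± 0.07. PFKM, the member that rose, and HK1 lost their calls with DESeq2 (0.227 and 0.178), without DMSO replicate 1 (0.351 and 0.283) and without STM2457 replicate 1 (0.152 and 0.182). PFKP lost its call with DESeq2 (0.0649) and without STM2457 replicate 1 (0.114), and GPI without DMSO replicate 1 (0.0613). The list was called at an adjusted p of 0.00109, with adjusted p = 0.686 with an estimated correlation. In the pentose phosphate pathway 3 of 11 tested genes fell (3 when adjusted over the list alone). TKT, a transketolase of its non-oxidative arm, fell by 0.38 ± 0.07. The others, PRPS1 and H6PD, lost their calls with DESeq2 (0.223 and 0.336), without DMSO replicate 2 (0.330 and 0.281) and without STM2457 replicate 1 (0.182 and 0.116). PRPS1 also lost it without DMSO replicate 1 (0.128) and H6PD without STM2457 replicate 2 (0.0822). This list had a median of -0.15 and an adjusted p of 0.0724, and was called without STM2457 replicate 2 (0.0184) and without a filter on low counts (0.0352).

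**Figure D1:**
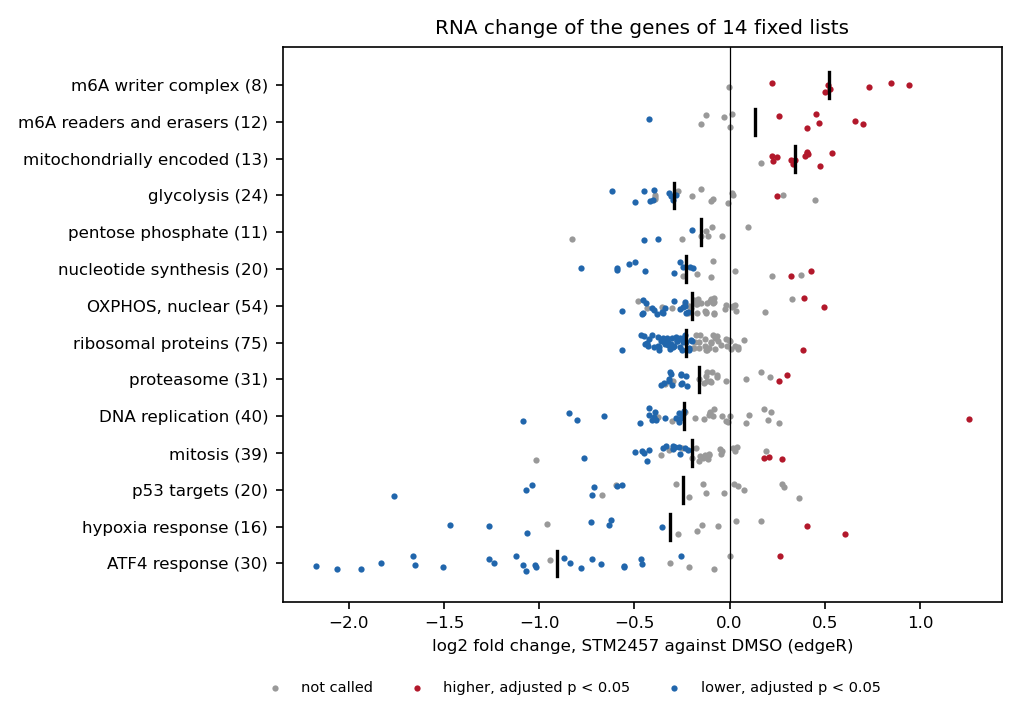
Log2 fold change with STM2457 against DMSO (x axis) of every tested member of 14 fixed gene lists (y axis, 1 list per line, number of genes in brackets), with red points called higher, blue called lower and grey not called by edgeR and a bar at each list median. The ATF4 list has its median at -0.91 and the writer complex at 0.52.

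Genes of the amino acid response made up the list with the lowest p. Of 30 tested targets of ATF4, a transcription factor of the integrated stress response, 24 fell and 1 rose, also when adjusted over the list alone, with a median of -0.91. SLC7A11, the cystine importer, fell from 174 ± 25.8 to 42.2 ± 12 CPM, at -2.06 ± 0.13. STC2, a secreted glycoprotein, fell from 153 ± 15.1 to 43.0 ± 0.517, at -1.83 ± 0.10. ASNS, asparagine synthetase, fell by 1.65, PHGDH, the entry enzyme of serine synthesis, by 1.09 ± 0.08 and AARS1, the alanyl-tRNA synthetase, by 1.12 ± 0.07. ATF4 mRNA fell by 0.55, and CEBPG, a dimer partner of ATF4, rose by 0.26. The list was called at an adjusted p of 7.5e-42, with adjusted p = 0.455 with an estimated correlation. Of 20 tested p53 targets 7 fell (8 when adjusted over the list alone), among them CDKN1A, an inhibitor of cyclin-dependent kinases, from 17 ± 3.30 to 4.88 ± 1.71 CPM, at -1.76 ± 0.27. SESN2, which is also in the ATF4 list, fell by 1.07 ± 0.10 and GADD45A by 1.04 ± 0.20, while MDM2 had a log2 change of 0.08. The list was called at an adjusted p of 3.8e-04, with adjusted p = 0.455 with an estimated correlation. Of 16 hypoxia-induced genes 7 fell and 2 rose, also when adjusted over the list alone. LOX, which crosslinks collagen, fell by 1.47 ± 0.19, the pyruvate dehydrogenase kinase gene PDK1 by 1.06 ± 0.13 and VEGFA by 0.73 ± 0.12, while EGLN1, an oxygen-sensing hydroxylase, rose by 0.61. This list was called at an adjusted p of 5.6e-04, with adjusted p = 0.455 with an estimated correlation. DESeq2 called 4 of the p53 targets and 5 of the hypoxia-induced genes.

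Of 40 replication genes 18 fell and 1 rose (20 and 1 when adjusted over the list alone). The primase subunit gene PRIM1 fell by 1.09 ± 0.16 and the polymerase gene POLA1 by 0.66, and the member that rose was FEN1, a nuclease of Okazaki fragment maturation, from 170 ± 13.5 to 406 ± 30.9 CPM. The list was called at an adjusted p of 4.3e-04, with adjusted p = 0.455 with an estimated correlation. Of 39 mitosis genes 15 fell and 3 rose (19 and 3 when adjusted over the list alone). HMMR, a spindle protein, fell by 0.76 and AURKB by 0.46, and BIRC5 rose by 0.28. Mitosis was called at 4.3e-04, with adjusted p = 0.686 with an estimated correlation. In nucleotide synthesis 11 of 20 genes fell and 2 rose (12 and 3 when adjusted over the list alone), with IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, down by 0.59 ± 0.07 and the uridine synthesis enzyme UMPS up by 0.43. This list was called at 0.00110, with adjusted p = 0.575 with an estimated correlation. Of 75 cytosolic ribosomal protein genes 42 fell and 1 rose (47 and 1 when adjusted over the list alone), with a median of -0.23, RPL14 at -0.56 ± 0.07 and RPL22 at 0.38. Their adjusted p was 1.4e-08, with adjusted p = 0.686 with an estimated correlation. Of 31 proteasome genes 13 fell and 2 rose (14 and 3 when adjusted over the list alone), with an adjusted p of 0.00868, adjusted p = 0.686 with an estimated correlation, and 0.168 without STM2457 replicate 1. DESeq2 called 1 of the 31 proteasome genes, 6 of the 39 mitosis genes, 13 of the 40 replication genes and 8 of the 20 nucleotide synthesis genes.

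Of the 13 messenger RNAs encoded in mitochondria 12 rose (13 when adjusted over the list alone), with a median log2 change of 0.34. MT-ND2, a subunit of complex I, rose from 1867 ± 42.1 to 2707 ± 21.7 CPM, at 0.54 ± 0.07. Mitochondrially encoded genes took 3.25% and 3.41% of the counts with DMSO and 4.08% and 4.28% with STM2457. Of 54 nuclear genes of oxidative phosphorylation 18 fell and 2 rose (21 and 2 when adjusted over the list alone), with NDUFB10 of complex I at -0.44, ATP5F1B, the catalytic subunit of ATP synthase, at -0.45 and UQCRFS1 of complex III at 0.50. The mitochondrial list was called at an adjusted p of 5.9e-05 and the nuclear list at 2.3e-04, both with adjusted p = 0.686 with an estimated correlation. DESeq2 called 6 of the 54 nuclear genes. The difference between these lists was not tested. None of the 13 called lists of 28 tested was kept with an estimated correlation. This cannot be put down to genes that vary together alone, since p also rose where the estimate lay below the preset 0.01. For p53 targets, at -0.0501, the unadjusted camera p went from 8.1e-05 to 0.0501. For readers and erasers, at -0.0756, it went from 0.00662 to 0.104. fry, which asks whether the members move one way on balance, passed for writers, readers, hypoxia targets and NRF2 targets, each at an adjusted p of 0.0482, and for p53 targets at 0.0147.

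The other 15 tested lists were not called. Their counts were the same when adjusted over the list alone, except for S-adenosylmethionine metabolism (3 lower, 1 higher), the tricarboxylic acid cycle (6 lower, 1 higher) and deadenylation (1 lower), and for the Hippo suppressors and chaperones, whose counts were 8 higher with 3 lower and 4 higher with 5 lower. The targets of NRF2, the regulator of antioxidant genes, had an adjusted p of 0.0692, with 2 of 14 lower, and were called without DMSO replicate 2 (0.0164), without a filter on low counts (0.00745) and with a replicate block (0.0211). S-adenosylmethionine metabolism had 0.263, with 2 of 8 lower and 1 higher. The tricarboxylic acid cycle had an adjusted p of 0.187, with 5 of 23 lower and 1 higher, among them OGDH of the 2-oxoglutarate dehydrogenase complex at 0.76 ± 0.10, and was called down without STM2457 replicate 2 (0.0415). Immediate early genes had 0.732, with ATF3 at -1.02 ± 0.17 as the called member of 14. The deadenylation and decay factors had 0.660, with 2 of 19 lower, PAN2 and PUM2, and the call of PUM2 ended with DESeq2 (0.245) and without DMSO replicate 1 (0.131), DMSO replicate 2 (0.190) or STM2457 replicate 2 (0.213). Activators of the growth kinase complex mTORC1 had 0.769, with 4 of 17 higher and 2 lower, and its suppressors had 0.895, with 2 of 13 higher and 1 lower. DESeq2 called 2 of the activators and 1 of the suppressors. The suppressors that rose lost their calls with DESeq2 (0.0691 for STK11 and 0.281 for PIK3R1), STK11 also without STM2457 replicate 1 (0.0924), and PIK3R1 without DMSO replicate 1 (0.0604), DMSO replicate 2 (0.225) or STM2457 replicate 2 (0.140). Fibroblast markers, kept as a check for another cell type, had an adjusted p of 0.134, with 3 of 7 tested lower, and were called without DMSO replicate 2 (0.0377). These 3, COL3A1, COL5A1 and FBN1, lost their calls with DESeq2 (0.132, 0.287 and 0.389) and without DMSO replicate 1 (0.190, 0.0981 and 0.253). COL5A1 and FBN1 also lost them without DMSO replicate 2 (0.0763 and 0.0835) and without STM2457 replicate 1 (0.280 and 0.202), and FBN1 without STM2457 replicate 2 (0.0784). Of 13 tested interferon-response genes, edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 by DESeq2, and of 6 drug efflux genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Replication-dependent histones had an adjusted p of 0.769, with 2 of 11 higher and 1 lower. Their median of -0.38 and mean of -0.22 were negative while the list test pointed up. The histone list was called down without DMSO replicate 1 (1.6e-12), without STM2457 replicate 1 (0.0150) and without a filter on low counts (2.5e-04), and up without DMSO replicate 2 (0.0164). For drug efflux the median was negative and the mean positive with a test pointing down, and for the mTORC1 activators the median was negative with mean and test positive. The mTORC1 suppressors had a positive median with mean and test negative. Olfactory receptors, blood, keratinised and hepatocyte markers had 0, 1, 2 and 0 members that passed the filter on low counts and were not tested. Histone, ribosomal protein and glycolysis genes have near-identical copies elsewhere in the genome, and how reads with several positions were counted is not given in the sources used here.

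MeRIP-seq asked which m6A regions were lost with the inhibitor. Of 17374 regions found in both DMSO lists, 10425 had an interval in both STM2457 lists, 4533 (26.1%) had none in either and 2416 (13.9%) had 1 in 1 of them. The lost regions with the highest fold over background, on the GRCh38 build, lay in VASH1, a gene of an inhibitor of vessel growth that also removes tyrosine from tubulin (chromosome 14, 76775894 to 76776234, fold 21.2), and in NHSL1 at 20.8. Next came FAM193A (chromosome 4, 2731698 to 2732187) at 19.9, LONRF1 at 19.8 and PPARA, a nuclear receptor of fatty acid oxidation, at 19.2. COX15 of heme synthesis had 19.1, XNDC1N, the kinase gene MAP2K1 and the splicing regulator gene PTBP3 had 18.9 each and the mannosidase gene MAN1A1 had 18.1. The kept regions with the highest fold were in MGAT5, a glycosyltransferase gene (chromosome 2, 134448641 to 134449937), at 102, ZNF724 at 92.4, TRIM59 at 90.1, the methyltransferase gene ICMT at 85.6, SLC35E1 at 82.8 and the hedgehog receptor gene PTCH1 at 77.7. Each fold is the lower of the 2 DMSO values, and the gene is the one whose span holds the region, without regard to strand. Of regions in genes with other regions, 4.37% of the kept, 5.81% of the lost and 10.4% of those absent from DMSO lay on the strand opposite to most of the gene's other regions, and the lost regions placed in NHSL1 and MAP2K1 lay on the strand opposite to these genes.

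The DMSO lists held 20032 and 20642 intervals (mean 20337 ± 431 SD, n = 2) and the STM2457 lists 16238 and 16234 (mean 16236 ± 2.83, n = 2), which was 20.2% fewer. The median fold over background was 8.25 and 8.62 with DMSO and 7.05 and 6.81 with STM2457. This difference was not tested, and an exact two-sided permutation test of 2 lists against 2 cannot give a p under 1/3. Between the DMSO lists, 12.3% of intervals on average had no partner, and between the STM2457 lists 20.3%. Of DMSO intervals 39.4% on average had no partner in an STM2457 list (38.8% to 39.9%), and of STM2457 intervals 19.8% had none in a DMSO list (19.0% to 20.5%). Intervals moved by 50 kb found a partner in 1.06% to 1.43% of cases. Of 12557 regions found in both STM2457 lists, 1156 (9.21%) were in neither DMSO list, with the highest fold in E4F1, at 36.0, then VWA1 at 15.2 and SLC12A7 at 14.4, and those placed in E4F1 and SLC12A7 lay on the strand opposite to these genes. This share was 16.7% without STM2457 replicate 1 and 17.1% without STM2457 replicate 2, where 1 list is enough to make a region. The share of DMSO regions lost was 57.2% in the lowest quartile of DMSO fold (95% exact interval 55.7 to 58.6, counting error only), 35.4% and 10.9% in the next quartiles and 0.806% in the highest (0.562 to 1.12).

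**Figure D2:**
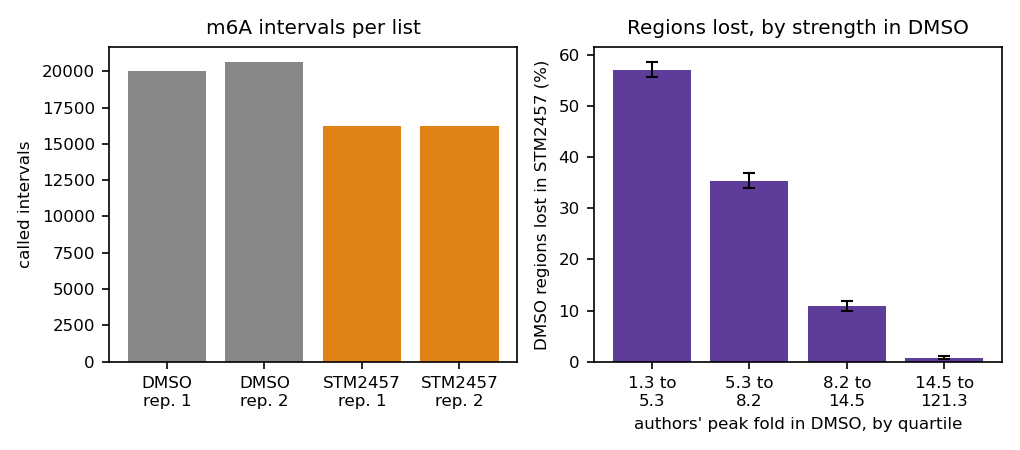
Called intervals per MeRIP-seq list (left, number of intervals, 1 bar per replicate) and the percentage of DMSO regions lost by quartile of DMSO fold (right, with 95% exact intervals). The lost share falls from 57.2% in the lowest quartile to 0.806% in the highest.

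The genes of the m6A machinery themselves held regions. In 7 of the 8 writer genes 19 DMSO regions were found, of which 14 were kept, 2 lost and 3 partly kept. All 6 regions of ZC3H13 were kept, as were those of fold 38.7 in RBM15 and 26.8 in RBM15B. The lost regions were in METTL14, at a fold of 4.61, and in RBM15B, at 5.16. In 11 of 12 reader and eraser genes there were 25 regions, of which 14 were kept and 8 lost, among them 1 in FTO at 6.27 and 1 in YTHDC2 at 13.3. Glycolysis genes held 15 regions in 9 of 24 genes, with 11 kept and 4 lost, the kept ones including PFKFB3, an enzyme that sets the level of the phosphofructokinase activator, at 36.9. The 4 lost regions of this list lay in PFKFB2, SLC2A3, PFKFB3 (fold 3.59) and PKM (fold 1.42). Pentose phosphate genes held 11 regions in 4 of 13 genes, with 8 kept, 1 lost in RPE and 2 partly kept, and H6PD had a kept region of fold 35.1. The 3 regions counted for TKT lay on the strand opposite to that gene, as did 1 kept region counted for PKM and 2 for HK2. Genes of deadenylation and decay held 30 regions, with 10 kept, 15 lost and 5 partly kept. Of all DMSO regions, 81.7% lay in the span of 1 coding gene and 6.95% in none, while 48.7% of regions moved by 1 Mb lay in the span of 1 coding gene. The last 10% of the span, read along the strand of the region and so the opposite end of the gene for regions on its other strand, held 37.4% of the kept regions (95% exact interval 36.3 to 38.4), 37.3% of the lost (35.7 to 38.9) and 11.4% of the regions absent from DMSO (9.33 to 13.7).

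The layers were joined to ask how RNA changed in genes with m6A regions. The 3444 genes whose DMSO regions were all kept had a median log2 change of 0.12, with 836 higher (24.3%) and 249 lower (7.23%). The 1197 genes whose regions were all lost had a median of -0.05, with 102 higher (8.52%) and 198 lower (16.5%). The 2612 other genes with DMSO regions, called mixed, held regions of different classes or partly kept regions, and had a median of 0.05, with 510 higher and 242 lower. The 3619 genes without any interval had a median of -0.10, with 214 higher and 593 lower. All 7253 genes with a DMSO region had a median of 0.07, with 1448 higher and 689 lower, and the matched genes without an interval had -0.10. Genes without an interval matched to the all-lost class had a median of -0.10 (95% of 10000 random lists from -0.12 to -0.0848), so the all-lost median lay above theirs. Among genes with a lost region were FEM1A, which rose by 2.0 ± 0.17, SPEN, a large repressor protein, which rose by 1.62 ± 0.10, and ID3, an inhibitor of helix-loop-helix factors, which rose by 1.53 ± 0.14. FLT1, ADM2, a peptide hormone, and TNC, a matrix protein, also held lost regions and fell by 3.38, 2.88 ± 0.58 and 2.76 ± 0.63. FLT1 was at 1.34 CPM with STM2457, and ADM2 and TNC had a mean log2 CPM of 1.76 and 1.28. At such low levels a lost region cannot be told apart from lost RNA. SPEN, ID3, ADM2 and TNC were chosen after their values were seen. The list test pointed up for genes with any DMSO region (adjusted p 4.7e-05, adjusted p = 0.0332 with an estimated correlation) and for all kept (9.3e-06, adjusted p = 0.0332 with an estimated correlation). It pointed up for the mixed class at 0.0271 (adjusted p = 0.117 with an estimated correlation) and down for all lost at 0.0271 (adjusted p = 0.171 with an estimated correlation). For all lost the estimated correlation was 0.0112, near the preset 0.01, so genes that vary together do not alone account for its higher p. The all-lost call ended without DMSO replicate 2 (0.0569), without STM2457 replicate 1 (0.0860) and with the stricter q (0.0730), and the mixed call without STM2457 replicate 1 (0.0528) and with the stricter q (0.0590).

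**Figure D3:**
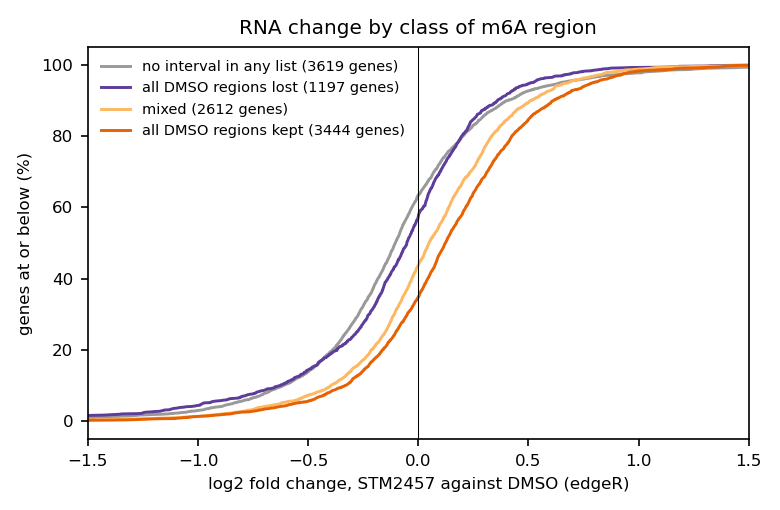
Cumulative share of genes (y axis) by log2 fold change of RNA with STM2457 (x axis, drawn from -1.5 to 1.5) for genes with all DMSO regions kept, with all lost, mixed (all other genes with DMSO regions) and without any interval. The medians are 0.12, -0.05, 0.05 and -0.10.

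The screen asked which gene knockouts changed growth with STM2457. It held 1 library per arm, so values are described without a p of replicates, and each gene value is the median log2 ratio of its guides with the SD between guides. Among the first genes by enrichment in the ranking of the authors' deposited table were FAM193A at 0.92 ± 0.33, MED13L, a subunit of the Mediator kinase module, at 0.94 ± 0.16, and STARD7, a lipid transfer protein of mitochondria, at 1.37 ± 0.36, each with an authors' FDR of 0.00124. They were followed by CENPM at 1.6 ± 2.67, the splicing regulator HNRNPA1 at 1.96 ± 0.84, FERMT2 at 0.72 ± 0.26, RPL38 at 1.20 ± 1.31, SAMD4B at 0.71 ± 0.09 and INTS4 at -0.12 ± 4.33. INTS4 rested on 1 guide at 8.27, CENPM had 2 of 4 guides up and -0.35 with guides of at least 50 counts, RPL38 had 0.35 with the same guides, and HNRNPA1 had a mean DMSO guide count of 16.9, a log2 ratio of 1.42 in the authors' deposited table, where 1 of its guides was at 0 in DMSO, and 1.17 with a pseudocount of 10. STK11, a kinase upstream of AMPK, had 0.97 ± 0.45 and an authors' FDR of 0.0421. The first genes by depletion were JTB at -1.94 ± 0.65 and ZC3H13 at -1.20 ± 0.88, both with an authors' FDR of 0.0173. Then came PYGM, the muscle glycogen phosphorylase, at -0.65 ± 0.33, AGER at -0.64 ± 0.11, RBM15 at -1.68 ± 0.79, KLRF1 at -0.71 ± 0.47 and RCE1 at -0.40 ± 0.11. RAB14 had -0.87 ± 0.93, MSTO1 -1.44 ± 0.21 and PCIF1, the methyltransferase of cap-adjacent adenosine, -0.33 ± 0.54. The authors' deposited table held 15 genes enriched and 2 depleted at an FDR under 0.05.

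Guides against the m6A writers were lower in STM2457. The median over the 8 genes was -0.92, and 0 of 10000 random lists of the same size and mean guide count had as low a median (95% of them lay between -0.23 and 0.22). METTL14 was at -1.82 ± 0.50, WTAP at -0.94 ± 0.42, VIRMA at -0.89 ± 0.43 and METTL3 at -0.72 ± 0.77, with CBLL1 at -0.26 ± 0.71 and RBM15B at 0.10 ± 0.38. Of the 8, 6 lay below the range of non-targeting guides taken 4 at a time (-0.26 to 0.27). For 1000 non-targeting guides the SD was 0.30 and 95% lay between -0.50 and 0.51. Of 19103 genes with 4 guides, 2740 (14.3%) lay above the range for 4 guides and 2863 (14.99%) below it.

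**Figure D4:**
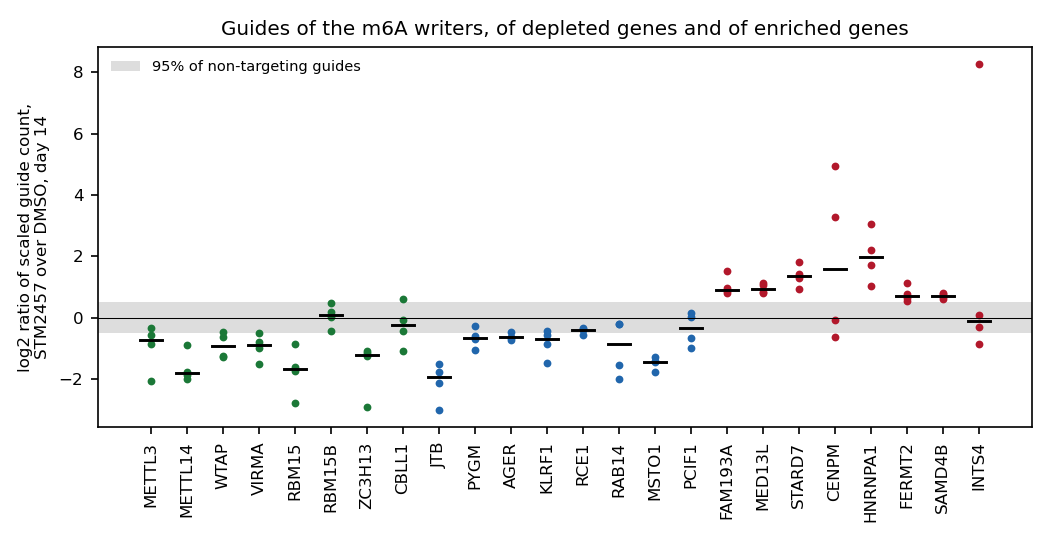
Log2 ratio of each guide's count in STM2457 over DMSO (1 library per arm) for the writer genes (green), 8 other depleted genes (blue) and 8 of the 10 first enriched genes, those in no fixed list (red), with a bar at each gene median. The grey band, from -0.50 to 0.51, holds 95% of the non-targeting guides.

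Glycolysis as a list had a median of 0.02 (12 genes above 0 and 12 below, percentile 63.7 of the random lists), or -0.0501 with guides of at least 50 counts and -0.0803 with the mean over guides. PFKFB2, which sets the level of a phosphofructokinase activator, was at 0.85 ± 0.31 with an authors' FDR of 0.113, GPI at 1.14 ± 1.36 with a mean DMSO guide count of 11.8, PKM at 0.63 ± 0.40 and PFKM at -0.41. The pentose phosphate list had a median of 0.05 (percentile 71.8), with 9 genes above 0 and 4 below. PGLS, a lactonase of the oxidative arm, was at 0.60 ± 0.56 and TKT at 0.50 ± 0.38, and TALDO1 was at -0.27 ± 0.09 and PRPS1 at -0.43. With guides of at least 50 counts PGLS was at 0.0359, the value of its lowest guide, TKT at 0.19, PKM at 0.42 and PFKM at -0.15. Mitosis lay at -0.23 (percentile 0.04), replication at -0.23 (0.16), the proteasome at -0.28 (0.305), the mTORC1 suppressors at -0.20 (0.585) and ribosomal proteins at -0.0511 (33.4). Examples were NDC80 of the kinetochore at -1.47 ± 0.87, the mitotic kinase PLK1 at -0.98 ± 0.40 and POLE2 at -1.12 ± 0.59. PLK1 was at -0.54 with a pseudocount of 10. With guides of at least 50 counts these percentiles were 1.55 for mitosis, 17.1 for replication, 8.45 for the proteasome, 45.6 for the mTORC1 suppressors and 14.9 for ribosomal proteins, with medians of -0.0241 for the mTORC1 suppressors and -0.21 for ribosomal proteins. Replication had a median of -0.12 with the mean over guides, and the proteasome -0.18 with a pseudocount of 10. ATF4 targets lay high at 0.11 (percentile 97.6), with ASNS at 0.59 ± 0.50 and SHMT2 of serine use at 0.57 ± 0.48, and histones lay at 0.10 (97.9). The tricarboxylic acid cycle was at -0.13 (2.9), with PDHA1 at -0.83 ± 0.48, and the Hippo suppressors at -0.12 (4.37), or -0.22 with guides of at least 50 counts. The other lists lay between the 6th and the 93rd percentile, at 7.08 for S-adenosylmethionine metabolism, 67.5 for readers and erasers, 62.5 for nucleotide synthesis, 11.6 for nuclear oxidative phosphorylation, 88.5 for p53 targets and 12.7 for interferon. They were 33.1 for endoplasmic reticulum chaperones, 13.2 for cholesterol synthesis, 18.6 for NRF2 targets, 85.2 for hypoxia targets, 30.5 for immediate early genes and 92.0 for deadenylation. They were 74.8 for mTORC1 activators, 21.8 for efflux, 86.6 for olfactory receptors, 38.1 for fibroblast, 10.6 for blood, 6.08 for keratinised and 21.1 for hepatocyte markers.

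The knockout check covered 13 genes with 24 guides, among them ARCN1, ARL1, FAM193A, GCN1, JTB, MED13L, PYGM, RARS1, SF3B1, STARD7, TRA2A and ZC3H13. The median share of reads with an insertion or deletion was 98.97% and the highest 99.7%. The lowest was 2.96%, for the first guide against SF3B1, a core splicing factor, where 15.8% of reads were altered and 12.9% carried substitutions alone. The other 23 guides had 87.8% to 99.7%, the lowest of them against RARS1. Deletions outnumbered insertions for 20 guides and insertions outnumbered deletions for 4, with 80.4% insertions for the first guide against FAM193A. Each guide had 1 value without replicates, and the depth behind the shares is unknown.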

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

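Summits within 100 nt in place of intervals were chosen after the data were seen, and the other alternatives before. Of the named genes in RNA-seq, 1426 values over the alternatives stayed on their side of the threshold, 83 lost and 13 gained a call and 1 reversed; for gene lists the numbers were 216, 24, 9 and 3. The list of histones reversed, with an adjusted p of 2.5e-04 without a filter on low counts and 1.6e-12 to 0.224 over the libraries left out, and the cause was not tested. H2AC11 reversed, at 0.16 without DMSO replicate 2, with a range of -2.54 to 0.16 over the libraries left out. DESeq2 called 1288 genes, 768 higher and 520 lower, and a log2 limit of 1 left 509, 225 higher and 284 lower. Leaving out 1 library gave 2119 to 3422 genes, 1202 to 1816 higher and 917 to 1606 lower. With the replicate block the count was 4148, 2214 higher and 1934 lower. The log2 limit removes genes by construction; for DESeq2 and the libraries left out the cause was not tested.

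For genes with all regions lost the adjusted p was 0.0730 with a -log10 q of at least 10, 0.171 with an estimated correlation and 0.0276 to 0.0860 over the libraries left out. For the mixed class these were 0.0590, 0.117 and 0.0183 to 0.0528, and the cause was not tested. The lost share of DMSO regions was 29.1% with that q in every list, 18.0% with it in the DMSO lists alone, 34.3% with reciprocal overlap, 27.8% with summits and 32.2% to 33.4% without 1 list. The kept share was 57.8%, 69.7%, 47.3%, 56.4% and 53.4% to 67.3% in that order. The share of STM2457 regions absent from DMSO was 6.43%, 13.9%, 16.3%, 10.8% and 10.8% to 17.1%. Leaving out a list, or a rule for the DMSO lists alone, changes what counts as a region by construction; for the others the cause was not tested. Place in the transcript and the DRACH motif, and the alternatives planned for them, were not run, since no genome sequence or exon annotation was at hand.

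At an authors' FDR under 0.01 the screen had 5 genes enriched and 0 depleted, and under 0.25 it had 75 and 12. Of the screen values per gene 852 stayed, 7 moved and 16 reversed, and of the list values 81 stayed and 12 moved. With guides of at least 50 counts CENPM reversed to -0.35, AHCY to -0.13, TPI1 to -1.10, ENO1 to -0.0574, RPE to -0.57, ATIC to -1.14, SDHC to -0.17, NDUFB11 to -0.25, OSGIN1 to -0.76 and FGB to -0.0612, and RRM1 to 0.17, DTYMK to 0.0740 and H2BC11 to 0.13. With the mean over guides ENO1 reversed to -0.13, OSGIN1 to -0.0823 and EIF4E to -0.0592. Guides with few reads were left out by construction in the former. The value left for AHCY, TPI1, RPE and NDUFB11 equals that of their lowest guide, and for RRM1 that of its highest. This limit acts on the DMSO count alone, and random lists moved down with it. Those matched to the proteasome list went from a median of -0.0208 to -0.139. The cause was not tested otherwise. Read depth was not known for MeRIP-seq and the knockout check, which leaves their counting error open.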

Other observations

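All tests of explanations below were chosen after the result was seen, except that on the strength of the DMSO region. Several genes had values in more than 1 kind of data. In S-adenosylmethionine metabolism, which supplies the methyl donor of m6A, METTL16, a methyltransferase that controls MAT2A splicing, rose from 92.7 to 149 CPM (log2 change 0.69 ± 0.09). AHCYL1 fell by 0.59 ± 0.07 and AHCY, the hydrolase of the by-product, by 0.32 ± 0.06, while MAT2A, the donor's synthetase, had -0.04 ± 0.07. In the screen (1 library per arm) MAT2A was at -1.36 ± 0.68 with 4 of 4 guides down, AHCY at 1.0 ± 0.58 and METTL16 at -0.82 ± 0.55. With guides of at least 50 counts AHCY was at -0.13, the value of its lowest guide, and METTL16 at -0.42. JTB, the first depleted gene of the authors' deposited table, rose in RNA-seq from 7.31 to 12.8 CPM (adjusted p 0.0349, edgeR), and its only DMSO region was lost. STARD7 rose by 0.37 (adjusted p 3.5e-04) with 1 of 2 regions lost, and FAM193A, with 1 of 2 lost, had -0.20 (adjusted p 0.254), and the calls of JTB and STARD7 were not tested under the alternatives. Across 12000 genes the screen and RNA changes had a Spearman rho of 0.0279, and genes are not independent replicates.

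Of 17 Hippo pathway suppressors 6 rose and 1 fell (8 and 3 when adjusted over the list alone), with KIRREL1 at 0.52, the kinase gene LATS1 at 0.42 and AMOT, a scaffold of YAP, down from 1005 ± 183 to 535 ± 141 CPM, and an adjusted p of 0.229. Of 20 chaperones and unfolded protein genes 3 rose and 5 fell (4 and 5 when adjusted over the list alone), with XBP1, a transcription factor of that response, at -0.88 ± 0.10, HERPUD1 at -0.90, SDF2L1 at 0.76 and an adjusted p of 0.769. Of 23 cholesterol synthesis genes 5 rose and 6 fell, also when adjusted over the list alone, with SC5D at 0.69 and the regulator SREBF2 at -0.41, and an adjusted p of 0.769. DESeq2 called 2 of the Hippo suppressors, 7 of the chaperones and 6 of the cholesterol genes, and the calls of AMOT (0.0535) and LATS2 (0.103) ended with it. Among genes with called RNA changes, 757 held a lost region, 401 higher and 356 lower.

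The first pattern is the loss of 26.1% of the DMSO regions. Lower RNA does not account for all of it, since 14.8% of the lost regions lay in genes called lower, against 8.33% of the kept. Regions falling under the caller's threshold may contribute, since 0.806% were lost in the strongest quartile, and a partial fall of m6A would give the same. Shallower reads cannot be told apart from the treatment, since 9.21% of STM2457 regions (95% exact interval 8.71 to 9.73) were absent from DMSO and the lists hold no depth. Per the labels samples were pooled before the pulldown, which would act alike on samples of 1 pool, but which samples shared a pool is not given in the sources used here.

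The second pattern is the higher RNA of genes whose DMSO regions were kept in full or in part, while genes with all regions lost differed from genes without an interval by 0.00191 ± 0.0147 (SE) with span and expression in the model, and had a median of -0.05 against -0.10 in genes without an interval matched on expression. Region calling that follows RNA level in the STM2457 lists cannot enter the contrast of genes with against without a DMSO region, since these classes come from DMSO alone. These genes differed by 0.15 ± 0.01 (SE) with span and expression in the model, a contrast that by construction does not test such calling. For lost against kept genes, at -0.22 ± 0.01, such calling cannot be told apart, since the classes use the STM2457 lists. The strength of the region is not the whole of it, since among genes with 1 region lost and kept differed by -0.16 ± 0.02 with fold in the model. All SEs of these models take genes as independent units, which they are not. They do not cover the spread between replicate libraries and may understate the error. No biological explanation was tested.

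The third pattern is the depletion of guides against the writers. Low guide counts are argued against, since the median was -0.96 with guides of at least 50 counts, where 95% of random lists lay between -0.26 and 0.18. A general growth difference was not excluded. The lowest of 4 lists of genes needed for growth was at -0.27 with the same guides (SD of random lists 0.11), above the writers. These lists were mitosis, replication, proteasome and ribosomal proteins. But this limit removes guides with few DMSO reads and left 55 of 75 ribosomal protein genes. Without it mitosis, replication and the proteasome also lay low, at percentiles 0.04, 0.16 and 0.305. Outlying guides are argued against, since 68.8% of the 32 writer guides lay below -0.50 and 28 lay below 0. The range that holds 95% of the non-targeting guides starts at -0.50. That of guides aimed at genes was wider, from -1.13 to 1.09. No biological explanation was tested, and a chance difference between the 2 libraries stays open since no replicate exists.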
